A study of Mus musculus with 2 samples.

How the data were processed

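Total RNA was taken with Trizol from bone marrow derived macrophages of C57BL/6 mice that were left untreated or given IL-36 gamma, and sequenced after a standard Illumina library preparation, per the labels' protocols. Each group had 1 library. The deposited values are raw counts per Ensembl gene, made by the authors and not normalized. Per the submitters' processing notes, the tools were FastQC 0.11.8, Trim Galore 0.6.1, STAR 2.5.0a and HTSeq on the mouse build mm10. The HTSeq version and settings, the annotation release and the strand setting are not given in the sources used here.

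Each library's counts covered 54446 genes and 5 rows of the counter that name no gene, which were kept out of library sizes and tests. Over genes and these rows together, the control library summed to 39260805 and the IL-36 gamma library to 38447743. Of these, 47.2% and 46.3% were assigned to no gene by the counter, 1.79% and 1.84% were ambiguous between genes and 6.65% and 6.92% had more than 1 alignment. Whether the reads assigned to no gene lie outside genes cannot be told, since the strand setting is not given. The gene counts were 17426367 and 17267900, and the 10 most abundant genes took 13.4% of each. Gene symbols, positions, exon lengths and GC content came from GENCODE M21 on the same assembly, in which 54409 gene IDs were found without their version number.

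Strand was checked with genes that have at least 90% of their exonic bases inside exons of 1 gene on the opposite strand. Where at least 50 counts would follow from the density of the overlapping partner, the median density was 1.48 times that of the partner in the control (96 genes) and 1.56 times in the IL-36 gamma library (95 genes). Reads of a gene and of its partner on the other strand therefore cannot be told apart in these counts, and antisense genes are reported as uncertain. Of the measured genes, 5410 (37.6%) have some exonic overlap on the opposite strand.

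Counts were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3 (1.02 for the control and 0.981 for IL-36 gamma). No edgeR test was run, because 1 library per group leaves no residual degrees of freedom. In its place a rule of size was used. For each gene with a mean count of at least 10 the ratio of scaled counts was computed with its exact 95% Clopper-Pearson interval. A gene passed when the whole interval lay above 2-fold or below 0.5. Polymerase chain reaction copies are not independent molecules, and culture to culture variation was not measured, so intervals and floors cover counting error only. The floor of 3 counts equals 0.169 CPM in the control and 0.177 CPM in the IL-36 gamma library.

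Gene lists for 56 pathways, cell types and signs of RNA quality held 982 names, of which 5 had no single matching gene and 4 were matched through a RefSeq synonym. A list was summarised by the median log2 ratio of its measured members with a prior count of 2. Its percentile came from 10000 random lists of the same size, drawn from measured genes in 20 bins of mean expression. A list counted when it had at least 5 members and a median within the upper or the lower 0.5% of random lists. Counting intervals of list medians came from 1000 Poisson redraws. In the text, a member above or below 1 has its whole counting interval on that side.

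The named genes follow a fixed rule. They are the 15 protein-coding genes higher and the 10 lower, ranked by the bound of the interval nearest 1, among genes past the size rule with at least 50 counts in the higher library, which left 6 and 5. To these were added the IL-36 receptor and ligand genes, up to 5 members of each list that stood apart and up to 3 members past the size rule of each other list. The 5 most abundant genes of each library and, where no member passed, up to 3 members closest to a list's median completed the rule. Values of some members of the lists are not reported here.

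The alternatives were total counts, DESeq2 1.42.0 size factors and upper quartile scaling, lowess trends on expression, GC content or length removed with a span of 0.3, other count filters, thinning of the deeper library, protein-coding genes only, other fold bounds and interval levels, other prior counts, a floor for genes at 0, unmatched random lists, other percentile bounds and the mean of each list. Random lists matched on expression in 10 bins and length in 5, and the exclusion of genes overlapped on the opposite strand, were chosen after seeing the data.

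The size rule was tested on simulated Poisson libraries with 197 changed genes among 14398. It passed 0 of 49 genes changed 1.5-fold, 86% of 50 changed 3-fold, 89.8% of 49 changed 4-fold and 98.0% of 49 changed 8-fold, and 0 of 14201 unchanged genes. The interval covered the simulated fold in 95.5% of genes. Of 20 simulated lists shifted by a log2 ratio of 0.3, 20 were placed beyond the bound, against 3 of 200 lists that were not shifted. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures matplotlib 3.10.9.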

Results

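The series measured messenger RNA in macrophages grown from the bone marrow of C57BL/6 mice, with and without exposure to IL-36 gamma, a cytokine of the interleukin-1 family. The question is which transcripts differ between untreated macrophages and macrophages given this cytokine. There was 1 untreated control library and 1 IL-36 gamma library. The dose and the duration of exposure are not given in the sources used here. The control library held 17426367 counts in genes and the IL-36 gamma library 17267900, over 21629 and 21048 genes with at least 1 count. With 1 library per group, no difference below has a replicate check and no p-value is given. Every interval is a 95% exact (Clopper-Pearson) interval of the ratio that covers counting error only, and each ratio is IL-36 gamma over control after scaling. A gene with 0 counts could still lie at up to 0.169 CPM (counts scaled to a common library total) in the control library or 0.177 CPM in the IL-36 gamma library, the levels of 3 counts. The lysozyme gene Lyz2 was the most abundant, with 404546 counts in the control and 380329 with IL-36 gamma, and the apolipoprotein gene Apoe had 363081 and 291222. The ferritin genes Fth1 (271320 and 337075 counts) and Ftl1 (230468 and 263746), the protease gene Ctsb (233971 and 235635) and the saposin precursor gene Psap (233031 and 226210) followed.

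Macrophages given IL-36 gamma carried more transcripts of a dicarboxylate transporter, an acute-phase protein, a protease inhibitor and a class I molecule. They carried fewer transcripts of macrophage elastase, a haemoglobin scavenger receptor and the transcription factor Egr2. Of 14379 genes with a mean count of at least 10, 11 were higher and 13 lower by more than 2-fold over their whole interval. Among these were 9 and 8 protein-coding genes. The number of genes whose interval lay wholly on 1 side of a ratio of 1 was far larger, 2907 above (20.2%) and 2375 below (16.5%), so most differences between the libraries were small. With scaling by total counts alone, 8 genes were higher and 16 lower, so that the higher share moved from 45.8% to 33.3%. Libraries simulated without any change, as Poisson counts at the same depth, gave 0 genes higher and 0 lower. They hold counting error only. At 10 CPM or more the standard deviation of log2 ratios was 0.224, against 0.0865 from counting error alone. The simulation therefore does not show how many genes 2 untreated cultures would place past the rule.

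Among the higher genes, Slc13a3 (ENSMUSG00000018459, chromosome 2, 165405028 to 165473230, mm10), which encodes a sodium-coupled dicarboxylate transporter, went from 8608 to 22096 counts, a ratio of 2.69 (2.63 to 2.76). Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), an acute-phase serum amyloid A gene, went from 3061 to 7193 counts, a ratio of 2.47 (2.36 to 2.57). The protease inhibitor gene Serpina3g (ENSMUSG00000041481, chromosome 12, 104236245 to 104241939) rose from 36 to 132 counts, 3.85 times (2.64 to 5.73). Nrxn2 (ENSMUSG00000033768, chromosome 19, 6418731 to 6544169), a cell adhesion gene known from neurons, rose from 86 to 232 counts, 2.83 times (2.20 to 3.67). H2-Q6 (ENSMUSG00000073409, chromosome 17, 35424850 to 35430055), a non-classical class I gene, rose from 145 to 360 counts, 2.61 times (2.14 to 3.18). Serpina3g and H2-Q6 have close paralogs, and their values are uncertain because reads could be split between such copies or left uncounted, which was not measured here. Ndrg1 (ENSMUSG00000005125, chromosome 15, 66929318 to 66969640), a gene induced by low oxygen and other stress, rose from 3856 to 7852 counts, 2.14 times (2.06 to 2.22). The antisense gene Gm17035 (1201 and 2501 counts, ratio 2.19) has all 419 of its exonic bases inside Ndrg1 exons on the opposite strand, so the pair cannot be told apart here. Of Nrxn2, 889 of 13812 exonic bases overlap exons of the opposite strand. Genes past the size rule on fewer than 50 counts were Elane and Enpp2 (each 3 and 22 counts) and the palmitoyltransferase gene Zdhhc23 (6 and 29 counts). The unclassified gene Gm38383 (45 and 175 counts) was the remaining one.

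Among the lower genes, Mmp12 (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499), which encodes macrophage elastase, fell from 11107 to 4332 counts, 2.44-fold (2.36 to 2.53). Egr2 (ENSMUSG00000037868, chromosome 10, 67535475 to 67542188), a zinc finger transcription factor, fell from 250 to 71 counts, 3.35-fold (2.57 to 4.43). Atp6v0d2 (ENSMUSG00000028238, chromosome 4, 19876841 to 19922605), a subunit of the vacuolar proton pump, fell from 503 to 196 counts, 2.45-fold (2.07 to 2.90). Cd163 (ENSMUSG00000008845, chromosome 6, 124304656 to 124330527), the scavenger receptor for haemoglobin bound to haptoglobin, fell from 618 to 249 counts, 2.36-fold (2.04 to 2.75). Matk (ENSMUSG00000004933, chromosome 10, 81252935 to 81263365), a tyrosine kinase gene, fell from 112 to 36 counts, 2.96-fold (2.02 to 4.44). On fewer than 50 counts, Il12b, which encodes the subunit shared by IL-12 and IL-23, went from 26 to 3 counts, a ratio of 0.121 (0.0235 to 0.395). Abca6 (25 and 3 counts) and the transcription factor gene Rfx3 (49 and 11 counts) were also lower. The other 5 lower genes were non-coding. Of Mmp12, 157 of 7237 exonic bases overlap exons of the opposite strand.

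**Figure D1:**
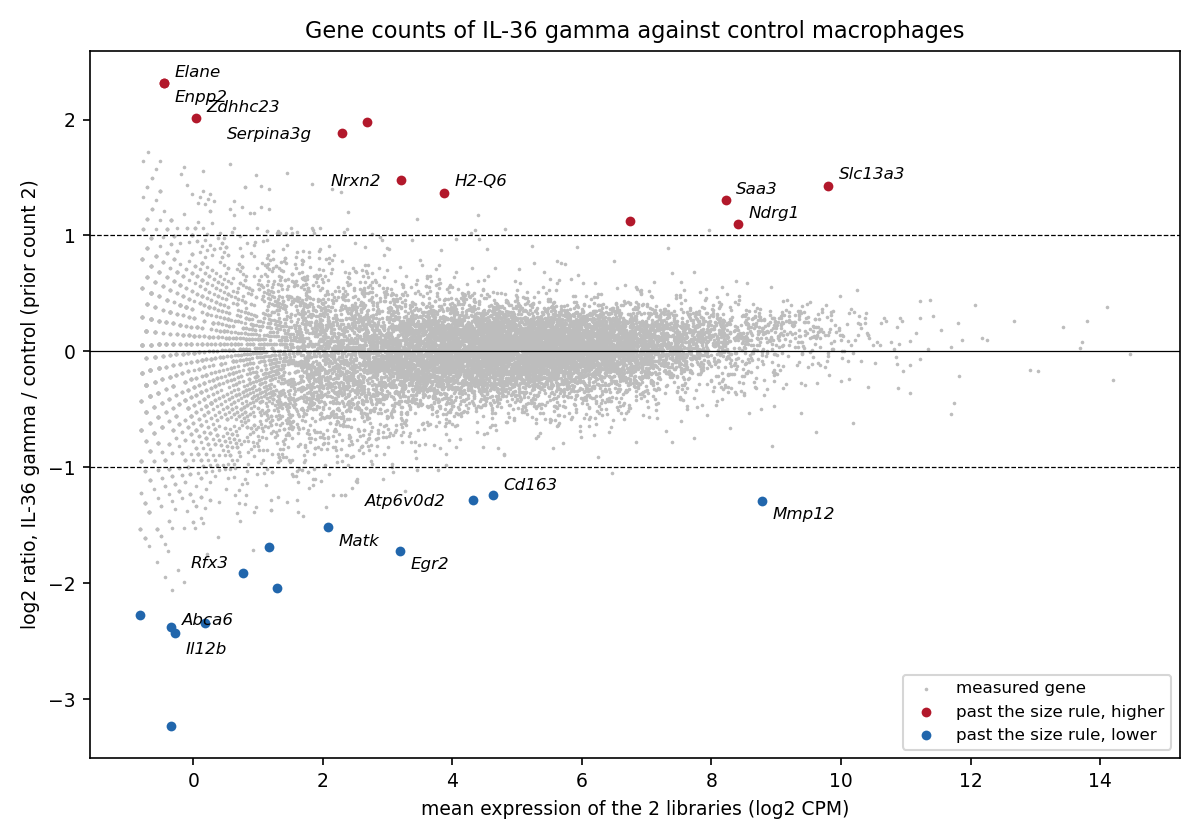
Each point is 1 of 14379 measured genes; the x axis is its mean expression in log2 CPM and the y axis its log2 ratio of IL-36 gamma over control with a prior count of 2. Coloured points are the 11 higher and 13 lower genes whose whole 95% counting interval lies beyond 2-fold, the protein-coding ones are named, and the dashed lines mark 2-fold; Slc13a3, Saa3, Ndrg1 and Mmp12 are the most abundant of the named genes.

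The size rule, the rule for named genes and 56 gene lists were fixed before the data were examined, and 51 of the lists had at least 5 measured members. Each list's median log2 ratio was placed among the medians of 10000 random lists of the same size and expression level. The median of 12 lists lay within the upper 0.5% of random lists and that of 3 lists within the lower 0.5%. By chance 0.51 lists in all would be expected if the members of a list varied independently. Genes of a pathway can vary together between any 2 cultures and some lists share members, so that number is no test of significance. The percentile describes these 2 libraries and not the conditions. Median ratios also followed gene length, from a log2 ratio of 0.13 in the second of 10 equal groups of genes ordered by exon length to -0.16 in the group of longest genes. Random lists of abundant genes had medians mostly above 0. Outside the upper and the lower 0.5%, these ran from 0.014 to 0.206 for the ribosomal protein list. For the macrophage identity list they ran from -0.024 to 0.231. Many members above 1, or a pooled ratio slightly above 1, therefore do not by themselves set abundant genes apart. The percentile takes expression level into account. Members of a list that are named outside the rule for named genes were chosen after their values were seen.

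**Figure D2:**
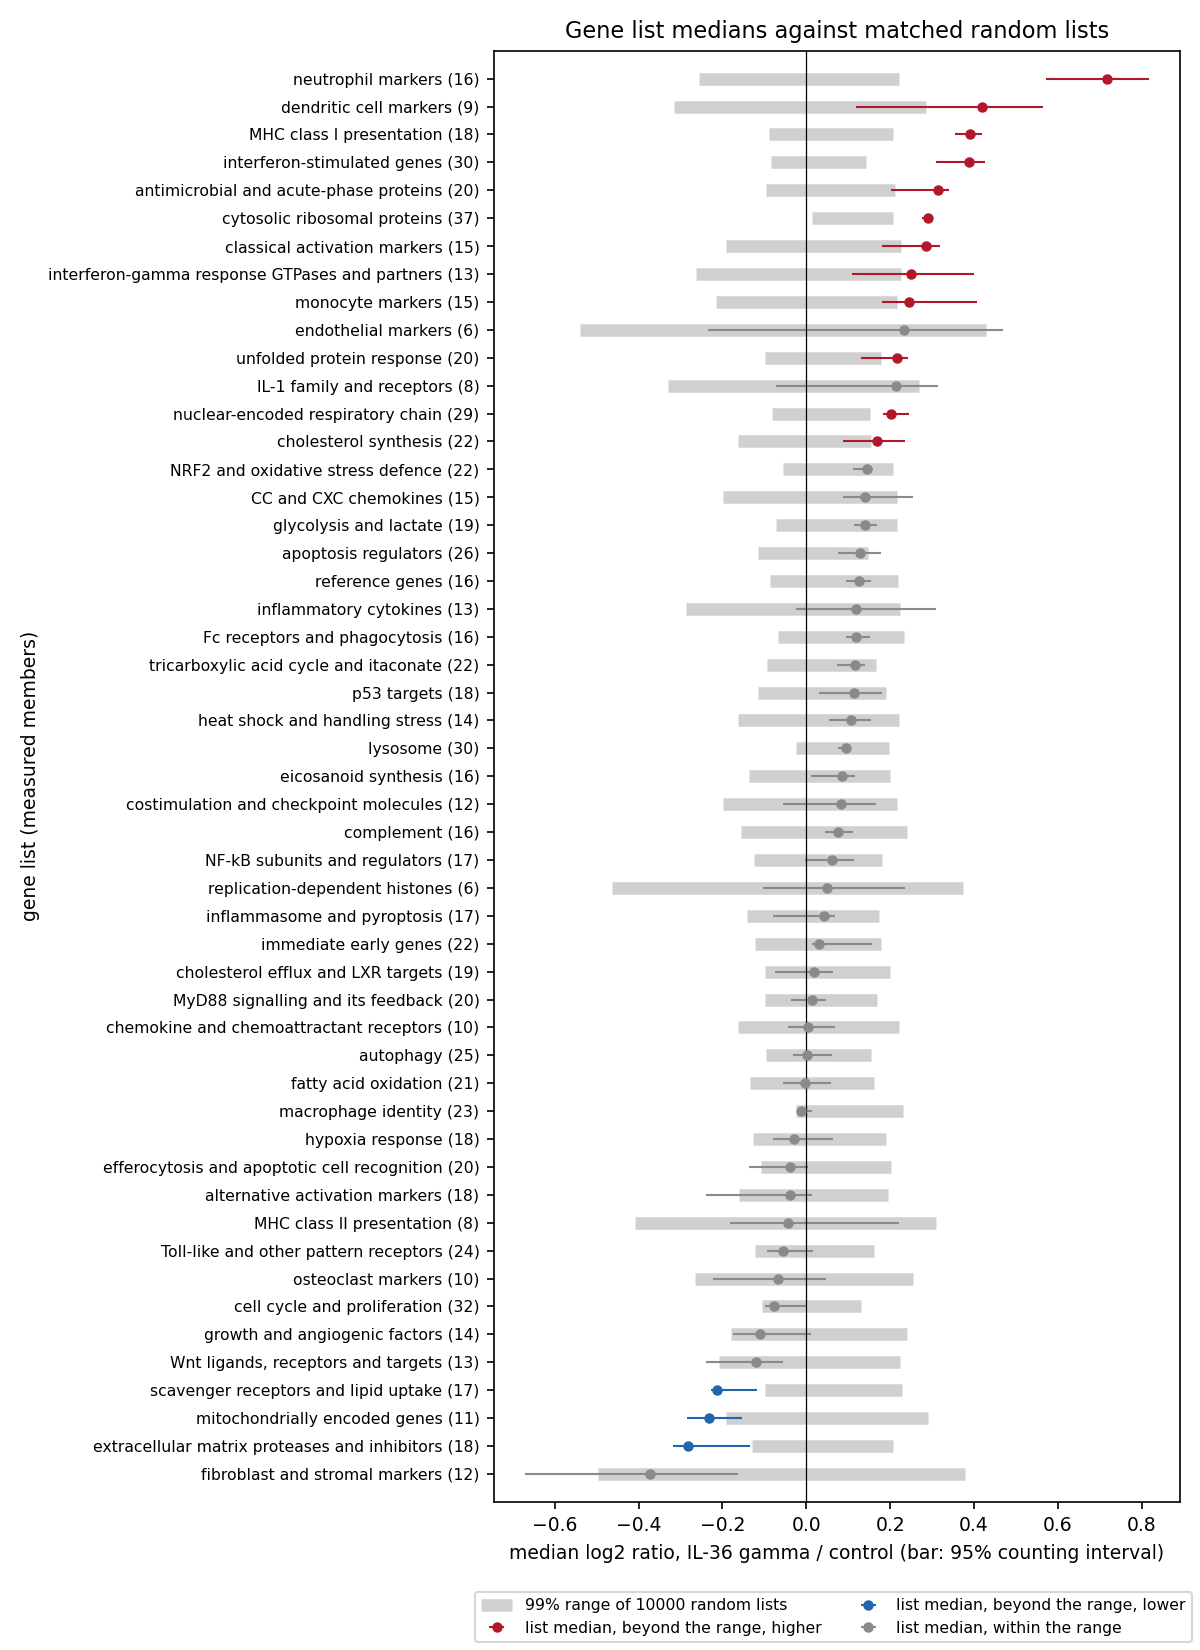
Each row is 1 of 51 gene lists with its number of measured members; points are median log2 ratios of IL-36 gamma over control, bars their 95% counting intervals, and grey bands the 99% range of 10000 random lists matched on expression. The 12 lists in red lie above and the 3 in blue below that range, with the neutrophil list highest at 0.72 and the extracellular matrix protease list at -0.28.

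Genes induced by interferon and genes of class I antigen presentation were higher in the IL-36 gamma library. Of 30 measured interferon-stimulated genes, 22 had an interval wholly above 1 and 2 wholly below it. Their median log2 ratio was 0.39 (0.31 to 0.43), above all 10000 random lists. Irf7, the transcription factor that amplifies type I interferon production, went from 2889 to 5682 counts, a ratio of 2.06 (1.97 to 2.16). The ubiquitin-like modifier gene Isg15 had a ratio of 1.65 (1.44 to 1.90), the nucleic acid sensor gene Zbp1 1.64 (1.46 to 1.86), Ifi44 1.74 (1.41 to 2.15) and the oligoadenylate synthase gene Oas1a 1.47 (1.38 to 1.56). Mx1 (ratio 0.823) and Parp14 (0.908) were the 2 members with an interval below 1. For class I presentation, 17 of 18 members had an interval above 1 and Nlrc5 did not, with a median of 0.39 (0.36 to 0.42), above all 10000 random lists. B2m, the class I light chain, had a ratio of 1.36 (1.34 to 1.37) and the proteasome activator gene Psme2 1.52 (1.43 to 1.61). Single values of Oas, Ifit and H2 genes, and of the Gbp genes below, which have close paralogs, are uncertain for the same reason. The GTPases and partners of the interferon gamma response had a median of 0.25, at percentile 99.79, with 6 of 13 members above 1 and 0 below. Gbp3 (ratio 1.58), Gbp6 (30 and 51 counts, 1.78, 1.12 to 2.90), Igtp (1.42), Gbp2 (1.38) and the feedback inhibitor Socs1 (1.42) led it. That call was lost when genes overlapped on the opposite strand were left out (percentile 99.25) and when no count filter was used (98.31). The 8 measured class II presentation genes had a median of -0.04 at percentile 42.74, with 2 above 1, H2-DMa (1.25) and H2-DMb1 (1.20).

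The lists of neutrophil markers and of antimicrobial and acute-phase proteins were higher with IL-36 gamma, each with some members lower. The neutrophil list had the highest median of all lists, 0.72 (0.57 to 0.82), above all 10000 random lists. Of its 16 measured members, 9 had an interval above 1 and 2 below. The calgranulin genes S100a8 (844 and 1274 counts, ratio 1.58) and S100a9 (676 and 1097, ratio 1.70) were higher, as were the granule genes Lcn2 (708 and 1139, ratio 1.69), Ngp (639 and 938, ratio 1.54), Ltf (442 and 644, ratio 1.53) and Camp (43 and 76, ratio 1.86). The neutrophil elastase gene Elane went from 3 to 22 counts. The collagenase gene Mmp8 (ratio 0.663) and Mmp9 (0.801) were lower. Of the 19 listed genes, 6 stand in another list as well and 8 had 10 CPM or more in the control library. The antimicrobial and acute-phase list, which shares 4 genes with the neutrophil list, had a median of 0.31 (0.20 to 0.34), above all 10000 random lists, with 14 of 20 members above 1 and 4 below. Beyond Saa3 it was led by S100a9, Lcn2, S100a8 and Camp. Lyz1 (ratio 0.768), Cybb (0.913) and Mpeg1 (0.888) were lower, and the interval of Lyz2 (0.987) also lay below 1.

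Monocyte and dendritic cell markers were also placed high, with members on both sides. The monocyte list had a median of 0.24 (0.18 to 0.41), at percentile 99.91 among random lists matched on expression and length, with 8 of 15 members above 1 and 2 below. Plac8 (33 and 89 counts, ratio 2.83), Ms4a4c (200 and 376, ratio 1.97) and the Ly6C gene Ly6c2 (125 and 233, ratio 1.96) were higher. The fibronectin gene Fn1 (ratio 0.559) and the transglutaminase gene F13a1 (0.581) were lower. The dendritic cell list had a median of 0.42 at percentile 99.96, with 4 of 9 members above 1 and 2 below. Bst2, which is also induced by interferon, had a ratio of 1.47, the actin bundler gene Fscn1 1.42 and Batf3 1.34. The integrin gene Itgax, the CD11c antigen of dendritic cells, had a ratio of 0.541. This call rested on few members and was lost without a count filter (percentile 97.36), at a mean count of at least 50 (96.255) and with the mean in place of the median (98.68).

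**Figure D3:**
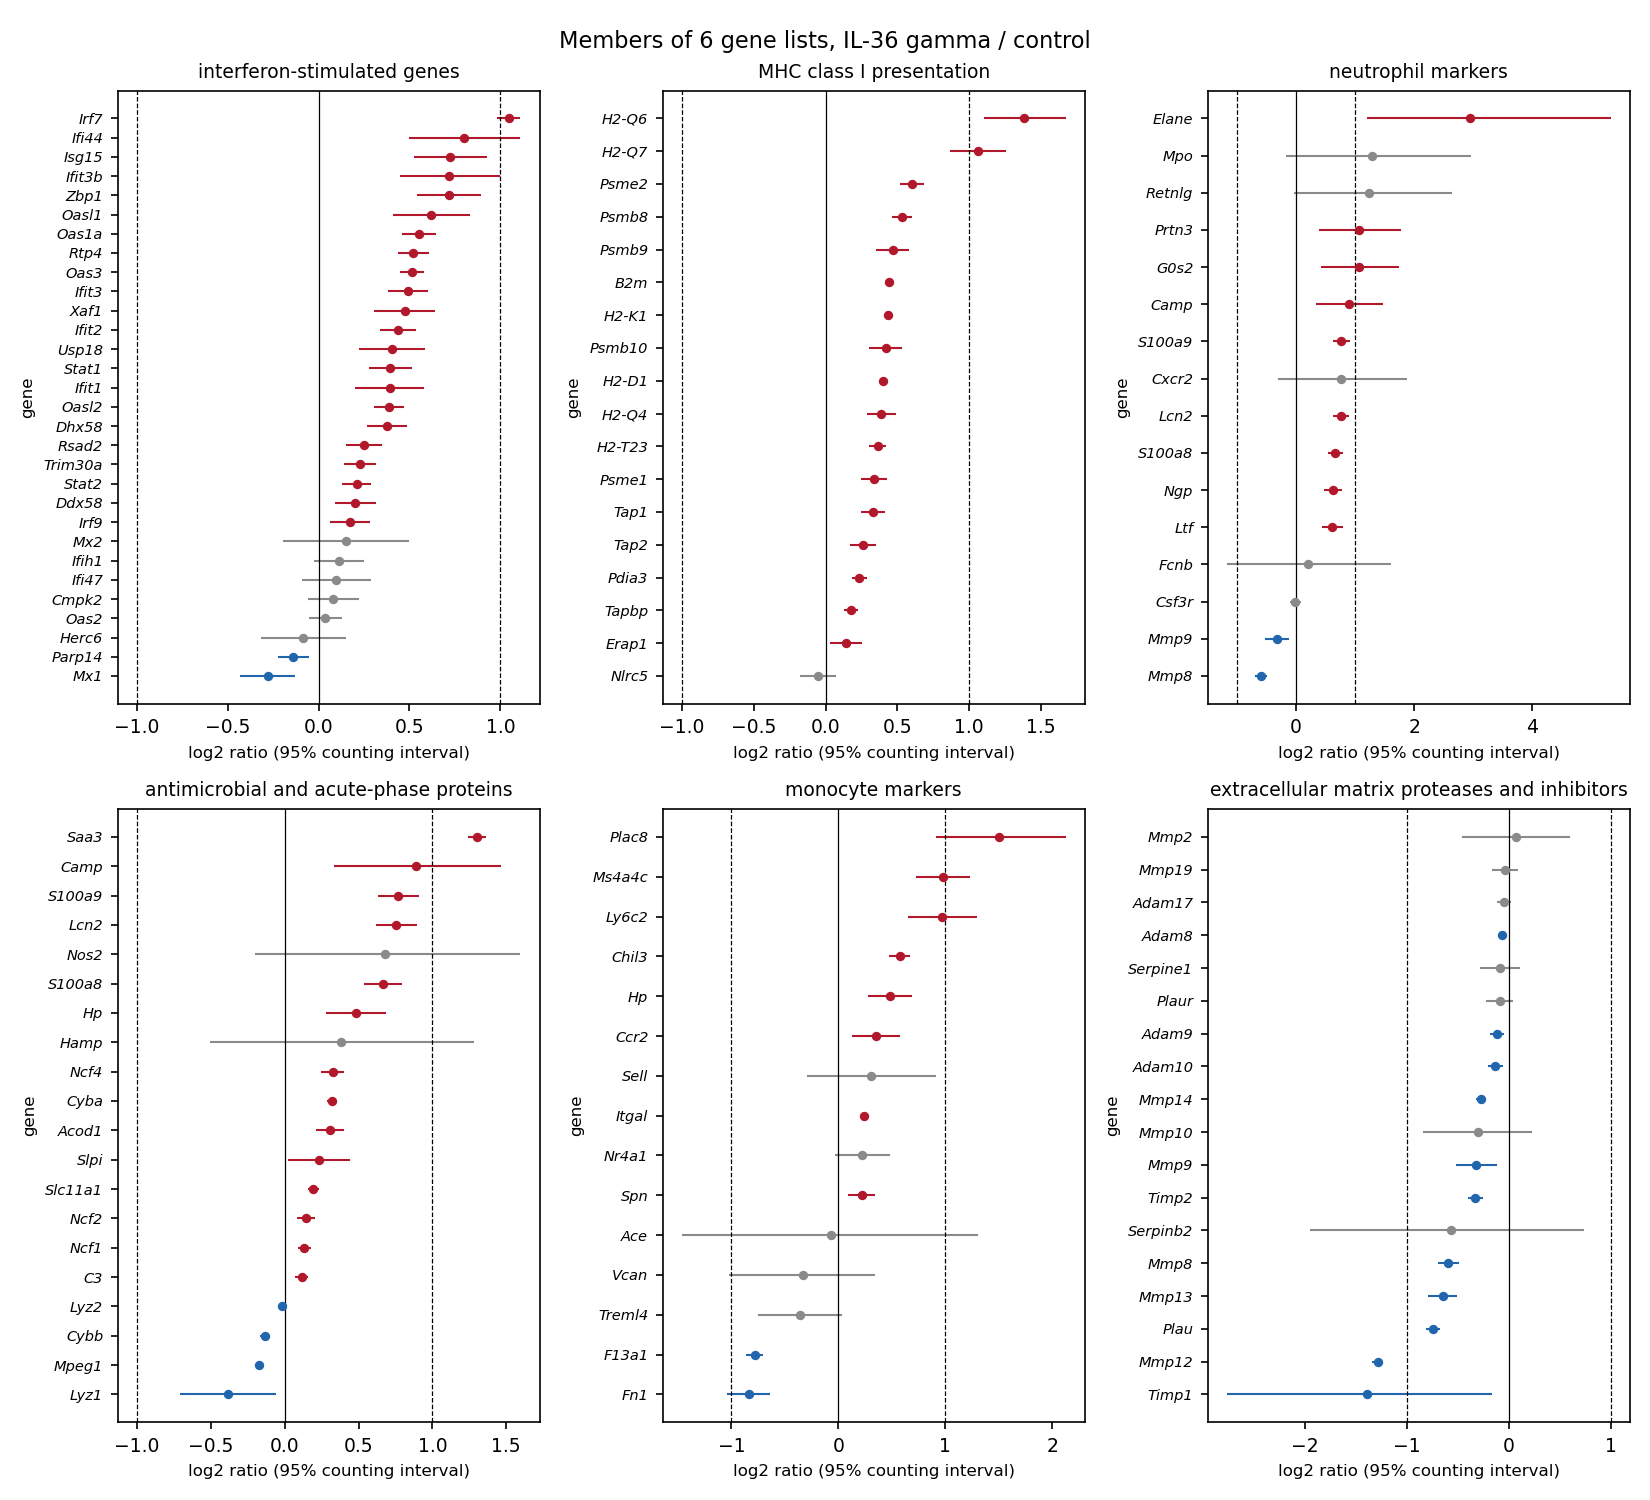
Log2 ratios of IL-36 gamma over control for the measured members of 6 gene lists, 1 panel per list and 1 gene per row, with 95% counting intervals as bars; red and blue points have an interval wholly above or below 0, and dashed lines mark 2-fold. In the class I panel 17 of 18 members have an interval wholly above 0, and in the panel of matrix proteases 11 of 18 have an interval wholly below 0.

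Genes of matrix breakdown and of scavenging were lower in the IL-36 gamma library. Of 18 measured extracellular matrix proteases and inhibitors, 11 had an interval below 1 and 0 above it. Their median log2 ratio was -0.28 (-0.32 to -0.13), below all 10000 random lists. After Mmp12, the urokinase gene Plau went from 4728 to 2682 counts (ratio 0.595), Mmp13 from 1061 to 645 (0.638), Mmp8 from 1907 to 1205 (0.663) and the inhibitor gene Timp2 from 3690 to 2800 (0.796). Mmp8 and Mmp9 belong to the neutrophil list too. The scavenger receptor and lipid uptake list had a median of -0.21 (-0.23 to -0.12), below all 10000 random lists, with 10 of 17 members below 1 and 3 above. Beyond Cd163, the endocytic receptor gene Stab1 went from 17284 to 10169 counts (ratio 0.618), Lrp1 from 69917 to 49049 (0.736), Colec12 from 836 to 530 (0.665) and the fatty acid binding protein gene Fabp4 from 624 to 402 (0.676). Marco (ratio 1.22) and Scarb1 (1.17) were among the 3 members above 1. Against random lists not matched on expression the scavenger call was lost, at percentile 0.565.

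Markers of macrophage activation were split. The classical activation list had a median of 0.28 at percentile 99.97, with 6 of 15 members above 1 and 2 below. Saa3, Marco, the formyl peptide receptor gene Fpr2 (1.27), Tnf (1.26), the itaconate synthesis gene Acod1 (1.24) and Irf5 (1.15) were above 1. Il12b and the costimulatory gene Cd86 (0.812) were below it, and Nos2 had 19 and 29 counts. By the mean of the list in place of its median the percentile was 90.83. The alternative activation list had a median of -0.04 at percentile 17, with 4 of 18 members above 1 and 7 below. Lower members besides Egr2 and Cd163 were the arginase gene Arg1 (1181 and 649 counts, ratio 0.577), the mannose receptor gene Mrc1 (ratio 0.672), Stab1, Fn1 and Clec10a (0.808). The higher ones were Chil3 (1.49), Klf4 (1.74), Il4ra (1.22) and the chemokine gene Ccl22 (1.98). By its mean this list lay at percentile 0.29.

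Lists of signalling below the IL-36 receptor did not stand apart, and that of the receptor and its ligands was too small to be placed. The receptor gene Il1rl2 (ENSMUSG00000070942, chromosome 1, 40324610 to 40367562) had 63 counts in the control and 45 with IL-36 gamma, a ratio of 0.750 (0.50 to 1.12). The co-receptor gene Il1rap (ENSMUSG00000022514) had 154 and 140 counts, 0.954 (0.754 to 1.21), and the inhibitory receptor gene Sigirr (ENSMUSG00000025494) 67 and 53, 0.830 (0.568 to 1.21). The gene of IL-36 gamma itself, Il1f9 (ENSMUSG00000044103), had 95 and 118 counts, 1.30 (0.987 to 1.73). Il1f6, Il1f8 and Il1f10 were too low to measure. This list had 4 measured members. The MyD88 signalling list (median 0.01, percentile 29.13) had 6 of 20 members above 1 and 3 below, with Irak1 at 1.01, Dusp1 at 1.02 and Map3k8 at 1.01. The NF-kB list (median 0.06, percentile 62.57) had 6 of 17 above 1 and 3 below, with Nfkb1 at 1.01, Rela at 1.04 and Chuk at 1.09. Among inflammatory cytokines (median 0.12, percentile 93.145), 6 of 13 were above 1 and Il12b was the 1 below. The anti-inflammatory cytokine gene Il10 went from 177 to 311 counts (1.84) and Tnf from 1381 to 1657, while Il1b (252 and 261 counts, 1.09) had an interval that includes 1. The inflammatory cytokine list was placed at 99.97 among genes with a mean count of at least 50, where Il12b is not measured. Without a count filter, where Il12b is included, it was placed at 99.87. Of 15 chemokine genes (median 0.14, percentile 93.835), 7 were above 1 and 2 below. Ccl2 had a ratio of 1.09, Ccl7 1.15 and Ccl9 1.10. The IL-1 family list (median 0.21, percentile 98.02) had 2 of 8 members above 1, Il18 (1.24) and Casp1 (1.28), and 1 below, the receptor antagonist gene Il1rn (2121 and 977 counts, 0.483). Among receptors for chemoattractants (median 0.00, percentile 27.77), 5 of 10 were above 1 and 4 below. C3ar1 had a ratio of 1.04, Ccr1 0.969 and C5ar1 0.922.

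The lists of cytosolic ribosomal proteins, the respiratory chain, the unfolded protein response and cholesterol synthesis were higher, and that of mitochondrially encoded genes lower. The ribosomal and mitochondrial lists were among 5 chosen as signs of RNA quality, and these 2 stood apart along with the other lists. With TMM scaling, all 37 cytosolic ribosomal protein genes had an interval above 1, with a median of 0.29 (0.27 to 0.30), above all 10000 random lists. Rpl19 had the highest ratio, 1.41 (1.34 to 1.48), and Rplp1 had 1.29 (1.26 to 1.31). Processed pseudogenes of these genes make their single values uncertain too. The nuclear-encoded respiratory chain list had a median of 0.20 at percentile 99.98, with 24 of 29 members above 1 and 1 below. Cox5a (1.41), Cox6b1 (1.25), Ndufa2 (1.27), Atp5c1 (1.21) and Atp5b (1.19) were among the higher members. Its percentile was 91.535 among random lists matched on gene length as well as expression, and 99.57 with the length trend removed. Mitochondrially encoded genes went the other way, with a median of -0.23 (-0.28 to -0.15) at percentile 0.29, 5 of 11 below 1 and 0 above. mt-Nd5 went from 14054 to 9263 counts (0.692), mt-Cytb from 15452 to 12151 (0.825) and mt-Co1 from 145671 to 124141 (0.894), and mt-Nd4 (0.833) and mt-Nd6 (0.851) were also lower. That list was placed at 1.78 once the trend with GC content was removed, 1.46 without genes overlapped on the opposite strand, 1.51 against unmatched random lists and 1.6 by its mean. The unfolded protein response list had a median of 0.22 at percentile 99.99, with 12 of 20 members above 1 and 2 below. Its leading members were the asparagine synthetase gene Asns (230 and 497 counts, 2.27), Trib3 (121 and 257, 2.23), the stress transcription factor gene Atf4 (1.29), the disulfide isomerase gene Pdia6 (1.26) and Atf3 (1.21). The percentile was 99.40 with the length trend removed. The cholesterol synthesis list had a median of 0.17 at percentile 99.79, with 8 of 22 members above 1 and 2 below. Its call was lost without genes overlapped on the opposite strand (98.37) and against unmatched random lists (99.39). Msmo1 (1.25) and Cyp51 (1.35) were among the members above 1, and Fdft1 (0.877) and Tm7sf2 (0.817) below.

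Markers of macrophages were abundant in both libraries and moved in both directions. The macrophage identity list had a median of -0.01 (-0.02 to 0.01) at percentile 0.98, with 11 of 23 members above 1 and 11 below. The pan-macrophage genes Adgre1 (1.14), Itgam (1.28), Fcgr1 (1.35) and Aif1 (1.45) were above 1, and Csf1r (0.809), Mertk (0.786), Cx3cr1 (0.682) and Mrc1 were below. The lysosomal marker gene Cd68 (0.991), C1qa (0.975) and Lyz2 lay close to 1. This list passed the lower bound when the trend with expression (percentile 0.105) or with length (0.02) was removed, and when random lists were matched on length (0.07). Osteoclast markers had a median of -0.07 at percentile 20.36, with 1 of 10 members above 1 and 2 below, and Atp6v0d2 past 2-fold. Markers of other cell types had low counts, with 10 CPM or more in the control library for 0 of 20 fibroblast, 2 of 14 endothelial, 2 of 16 B cell, 1 of 20 T and NK cell and 0 of 14 mast cell and basophil genes. Fibroblast and stromal markers had a median of -0.37 at percentile 3.85, with 3 of 12 below 1 and 0 above. Endothelial markers had a median of 0.23 at percentile 94.25, with 1 of 6 above 1, Pecam1 (509 and 617 counts, 1.27), and 2 below, Kdr (0.513) and Vwf (0.755). B cell markers had 4 measured members, T and NK cell markers 2, erythroid markers 2 and mast cell and basophil markers 0, too few to place any of them.

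Lists chosen as signs of RNA quality or handling were placed as follows, apart from the ribosomal and mitochondrial lists above. The heat shock and handling list had a median of 0.11 at percentile 81.89, with Hsp90aa1 at 1.07, Hspa1a at 1.09 and Hsp90ab1 at 1.07. The reference gene list had a median of 0.13 at percentile 80.43, with 11 of 16 members above 1 and 1 below. Sdha was at 1.09 and Pgk1 at 1.09. Replication-dependent histones had a median of 0.05 at percentile 66.73 over 6 members, with Hist1h4i at 1.02.

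**Figure D4:**
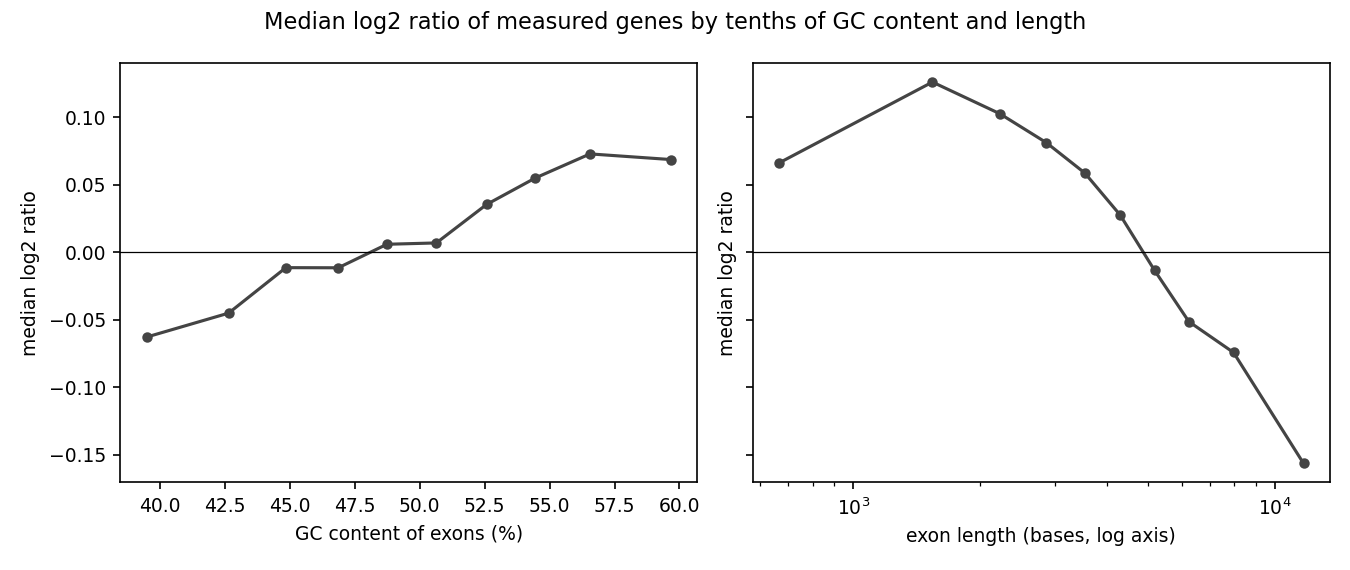
Median log2 ratio of IL-36 gamma over control in 10 equal groups of the measured genes ordered by GC content of exons in percent (left) and by exon length in bases on a log axis (right). The median runs from -0.06 to 0.07 between the groups of lowest and highest GC content, and from 0.13 to -0.16 between the second and the longest group by length.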

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

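The tests with random lists matched on length and the test of mature neutrophil genes outside the list were chosen after the patterns were seen. The other tests in this section also address patterns found in these same 2 libraries.

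Of the total of each library, with reads in genes and reads in none together, 6.92% had more than 1 alignment with IL-36 gamma, against 6.65% in the control (6.64% to 6.66%). A share of 1.84% was ambiguous between genes, against 1.79% (1.79% to 1.80%). Both shares stood above the control's counting interval, which is very narrow at these totals and does not cover variation between libraries.

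The neutrophil list had the highest median of the 51 lists. The trend with annotated exon length between the libraries does not account for it, since the list stayed at percentile 100 among random lists matched on expression and length. A higher share of mature neutrophils among the treated cells stays open. It would raise 10 neutrophil genes outside the list, and their pooled ratio was 1.1702 (1.05 to 1.30), wholly above 1. Padi4 (550 and 569 counts), Pglyrp1 (44 and 75) and Cd177 (29 and 47) were the most abundant. Padi4 and Pglyrp1 hold 87.4% of the counts, most of them from Padi4, so the pooled ratio mainly reflects Padi4, which changed little. Pglyrp1 and Cd177 rose more, on few counts, as did Olfm4 (4 and 9). Mmp25 (11 and 10), Stfa3 (6 and 5) and Stfa1 (2 and 1) did not rise. The set's median was placed at percentile 94.055. A higher share of granulocyte-monocyte precursors cannot be told apart from other sources. The pooled ratio of precursor genes outside the list was 1.099 (1.05 to 1.15), with a median at percentile 77.09. Of that set's counts, 96.1% came from Gstm1 and Mgst1, whose high baseline would hide a small share. The primary granule genes Elane, Mpo and Prtn3 had a pooled ratio of 2.61 (1.76 to 3.93), but they belong to the list and so to the pattern itself. Induction of the genes of the neutrophil list within macrophages by IL-36 gamma is the biological alternative and was not tested.

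The ribosomal protein and respiratory chain lists hold many short genes, and short genes were higher on the whole. Exon length here was that of all annotated exons of a gene together, not of the transcripts expressed. By that measure length accounts for too little of the ribosomal part, which stayed at percentile 99.995 among random lists matched on expression and length. The respiratory chain part, with a median of 0.20 (0.18 to 0.25), was placed at 91.535 among those lists but at 99.57 with the length trend removed (median 0.14), so that length and other sources cannot be told apart while these 2 tests differ. A shift of reads from processed pseudogenes to the ribosomal genes would lower the pseudogenes. These held 4002 counts in the control and 4088 with IL-36 gamma, against 376622 and 437409 in the ribosomal genes. Counts that few could not supply the rise of the ribosomal genes. The pooled ratio of the pseudogenes was 1.0722 (1.03 to 1.12) and so not below 1. Other sharing of reads is not decided by that ratio, since ribosomal reads misplaced on pseudogenes would rise along with the ribosomal genes. Reads with more than 1 alignment were not counted in genes at all. A response to IL-36 gamma in ribosomal protein transcripts stays open as a hypothesis, and a difference between the 2 cultures or preparations cannot be excluded with 1 library each.

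For the interferon and class I lists, 3 technical explanations were tested and none accounted for the pattern. The interferon-stimulated list stayed at percentile 100 among random lists matched on expression and length. Without members of multigene families, the median log2 ratio of both lists together was 0.2925 (0.24 to 0.34) over 24 genes, so reads shared between paralogs may add to single values but do not carry the whole pattern. Without members overlapped on the opposite strand it was 0.3962 (0.37 to 0.44) over 33 genes. The pattern may be biological, as a hypothesis found and tested on the same 2 libraries, and a difference between cultures was not tested.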

How the results depend on the processing

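Alternatives named as chosen after seeing the data were the exclusion of genes overlapped on the opposite strand and the matching of random lists on length. The main counts were 11 genes higher with IL-36 gamma and 13 genes lower with IL-36 gamma, and likewise 12 gene lists higher with IL-36 gamma and 3 gene lists lower with IL-36 gamma. No paired analysis was possible because each group has 1 library, and no library could be left out. A bound of 1.5-fold gave 50 genes higher and 76 lower, a bound of 4-fold 0 and 1, the point ratio beyond 2-fold 156 and 251, and the wider of 2 confidence levels 5 and 3, each through the construction of the rule. With genes overlapped on the opposite strand left out, 7 genes were higher and 8 lower, since those genes were not tested. The number of lower genes was 21 with no filter on counts and 5 at a mean count of at least 50, where more or fewer low genes were tested, and 8 among protein-coding genes, since the other 5 are non-coding. For lists, 5 were lower with the length trend removed, where the cause was not tested, and 5 at a percentile bound of 2.5, through the looser bound. The other scaling and trend settings gave 8 to 11 genes higher and 10 to 16 lower. Across all alternatives the 4 counts kept within 1.5 times the main value in 51 comparisons and moved further in 15. Scaling by total counts turned the split of genes to 33.3% higher, and removing the length trend turned that of lists from 80% to 68.75%.

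Of the 15 lists that stood apart, 7 did so in each of 17 settings, and none of the 15 changed the sign of its median. Some of these settings could hardly change a call. A change of scaling shifts a list and its random lists alike, and the floor for genes at 0 left the percentiles as they were. Lists that were lost in some setting are named with their percentiles beside each result. The apoptosis list passed the upper bound by its mean, as did chemokines (99.78), and the cell cycle list passed the lower bound with the length trend removed (0.42). Fibroblast markers were gained against unmatched random lists (0.04), and the IL-1 family (99.775) and inflammatory cytokines (99.87) without a count filter. Among the medians of lists 686 values stayed within their counting interval and 79 moved beyond it, and among named genes 1665 and 193. No scaling moved the median gene by more than 0.06 on the log2 scale (-0.0563 for total counts). Depth limits genes with few counts, and a simulated 3-fold change passed the size rule in 86% of genes.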

Other observations

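The test of the unfolded protein response list below was chosen after its members were seen.

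Several further gene groups did not stand apart from random lists but held members with larger differences. The hypoxia list had a median of -0.03 at percentile 15.69, with 3 of 18 members above 1, Ndrg1 among them, and 5 below, among them the hypoxia-inducible factor gene Epas1 (86 and 35 counts, ratio 0.427). Growth and angiogenic factors had a median of -0.11 at percentile 3.4, with 3 of 14 above 1 and 5 below. The osteopontin gene Spp1 went from 69599 to 45611 counts (0.688) and Igf1 from 7990 to 5276 (0.693), while Vegfa had a ratio of 0.915 and Hgf 0.937. The cell cycle list had a median of -0.08 at percentile 2.42, with 1 of 32 members above 1 and 7 below, and Mki67 had a ratio of 0.707. Wnt ligands, receptors and targets had a median of -0.12 at percentile 5.305, with 1 of 13 above 1 and 5 below, and Lrp5 had a ratio of 0.920. Apoptosis regulators had a median of 0.13 at percentile 98.63, with 13 of 26 above 1 and 2 below, and p53 targets a median of 0.11 at percentile 88.06, with 8 of 18 above 1 and 3 below. Immediate early genes had a median of 0.03 at percentile 45.71, with 7 of 22 above 1 and 3 below, Egr2 past 2-fold and its relative Egr1 at 0.689.

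Lists of uptake and defence did not pass the bounds either. Pattern receptors had a median of -0.05 at percentile 7.75, with 4 of 24 above 1 and 8 below, and Cd14 had a ratio of 0.956. Receptors for apoptotic cells had a median of -0.04 at percentile 6.47, with 4 of 20 above 1 and 9 below, among them Mertk, Stab1 and Axl (0.758). Inflammasome genes had a median of 0.04 at percentile 62.545, with 6 of 17 above 1 and 6 below. The adaptor gene Pycard had a ratio of 1.44 and the sensor gene Nlrp3 0.742. Complement genes had a median of 0.08 at percentile 53.625, with 8 of 16 above 1 and 4 below, and Fc receptors and phagocytosis genes 0.12 at 64.86, with 10 of 16 above and 3 below. Lysosome genes had 0.10 at 41.82, with 19 of 30 above and 4 below, and autophagy genes 0.00 at 23.37, with 4 of 25 above and 3 below. Costimulation and checkpoint molecules had a median of 0.08 at percentile 78.695, with Icam1 at 1.12 and Vsir at 1.07, and eicosanoid synthesis genes 0.08 at 76.89. In metabolism, glycolysis had a median of 0.14 at percentile 86.95, with 13 of 19 above 1 and 1 below, the tricarboxylic acid cycle 0.12 at 92.85, fatty acid oxidation 0.00 at 35.7 and oxidative stress defence 0.14 at 89.95. Cholesterol efflux genes had a median of 0.02 at percentile 23.105, with 6 of 19 above 1 and 7 below, and the efflux transporter gene Abca1 went from 11063 to 5999 counts (0.569).

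The leading members of the unfolded protein response list, Asns and Trib3, are known as targets of ATF4 in the response to amino acid shortage. A hypothesis is that the list was moved by that arm more than by protein folding, and these values do not decide it. Its 11 folding genes of the endoplasmic reticulum had a median of 0.14, at percentile 87.905, with 7 above 1 and 1 below. The 25 measured amino acid response genes outside the list had a median of 0.22, at percentile 100, with 16 above 1 and 1 below. The difference of the 2 medians, 0.08, lay at percentile 88.98 among differences between random lists of the same sizes and expression, within their range. The 6 genes of the ATF4 arm in the list had a median of 0.36 at percentile 99.93, with 5 above 1 and 0 below. The hypothesis was drawn from members of the same list, so that value does not test it.

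The X-inactivation transcript Xist had 1 count in the control library and 14 with IL-36 gamma, a ratio of 14.7 (2.24 to 621). Xist lay below the filter of a mean count of at least 10, and the source of its difference was not tested. The Y-linked genes Kdm5d (478 and 420 counts), Uty (425 and 443), Eif2s3y (844 and 810) and Ddx3y (1214 and 886) were present in both libraries. Ddx3y had a ratio of 0.766 (0.702 to 0.836), and the intervals of the other Y-linked genes named include 1. Primary granule genes of the neutrophil list, Elane, Mpo and Prtn3, had 37 counts together in the control and 92 with IL-36 gamma, a pooled ratio of 2.61 (1.76 to 3.93). Its 11 mature-stage genes had 4588 and 5295 counts, a pooled ratio of 1.21 (1.16 to 1.26), with 5 of 8 measured members above 1 and 1 below.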
